A study of Rattus norvegicus with 9 samples.

How the data were processed

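Total RNA was extracted from liver tissue with Trizol and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. The authors deposited 2 tables, one of high-fat diet and normal diet libraries and one of high-fat diet and SCL-treated libraries. Per the file headers, each holds raw counts per gene, counts divided by a size factor (a normalized signal), FPKM values, and the authors' log2 fold change, p-value and adjusted p-value. The submitters' processing notes name DESeq2, with no version, and the mouse genome build mm9. The aligner and counter are not given in the sources used here. Of the gene symbols in both tables, 92.7% matched a symbol or synonym of rat RefSeq genes (assembly GRCr8), and 316 carried AABR07 and 339 carried RGD names, so the build named in the notes was not taken as that of the counts. No coordinates are given. Whether the counting used strand is not given, so genes that overlap, or that share reads with a close copy such as the cytochrome P450, globin and immunoglobulin families, are uncertain.

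The tables held 15929 and 15819 genes, of which 15565 were in both and were analysed. Counts of the high-fat diet libraries did not differ between the tables for any shared gene. The 364 and 254 genes in 1 table only held at most 0.0019% of a library's reads and were left out. Library names follow the replicate numbers in the labels. Within each group the counts of every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 38.5 or more over genes with more than 20 reads in a pair, so no library was counted as a repeat of another. The depth of 12413774 to 15521648 reads limits precision for genes of low count, and a library with many mitochondrial reads has fewer left for other genes. Outside its 100 most abundant genes, SCL-treated replicate 2 held 3.81 M reads and high-fat diet replicate 1 held 7.69 M reads.

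The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. All 9 libraries entered 1 fit with group as the only term and 6 residual degrees of freedom. Genes were kept by filterByExpr with a minimum count of 10, which left 12041, and libraries were scaled by TMM. The quasi-likelihood test gave log2 fold changes, and the standard error was taken as the absolute log2 fold change divided by the square root of the F value. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. CPM values use the TMM-scaled library sizes. The first group named in a comparison is the numerator of its fold change.

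The 30 gene lists for liver metabolism, stress, inflammation and cell type markers were fixed before the data were examined. Lists with at least 3 tested genes, 29 of them, were tested with camera in limma 3.58.1, two-sided, at a preset correlation between genes of 0.01, and adjusted over the lists. An estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. Genes were also adjusted over the list alone. Some listed genes, such as Tnf, Il6, Elovl6 and Adipoq, were not analysed here. Values of some single genes named by the rule below are not reported.

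The rule for named genes was fixed at the same time. It takes the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean of at least 1 log2 CPM, groups that do not overlap and no predicted-locus name, in each of the 2 main comparisons. For each list it takes up to 4 called members, or the 2 most abundant where none is called, and for genes that moved back the 10 with the smallest larger adjusted p. Other genes are said to have been chosen after their values were seen.

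Alternatives fixed in advance were DESeq2 1.42.0, its size factors in edgeR, library totals alone, no count filter, only the 6 libraries compared, a replicate block, each library left out in turn, stricter thresholds and limma-voom with quality weights. Chosen after seeing the data were the log2 mitochondrial share as a covariate, removal of the 2 libraries over 40% mitochondrial, and removal of mitochondrial transcripts before scaling. The edgeR and DESeq2 steps were tested on simulated counts with genes changed by known folds. Opposite changes in 2 comparisons that share libraries were set against 10 simulations without effects. Both kinds of simulation drew each gene independently of the others. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.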

Results

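Liver RNA of male rats, of the strain labelled SD, was sequenced in 9 libraries. The normal diet group, the high-fat diet group and the SCL-treated group each held 3 libraries. SCL is the labels' short form for the plant Smilax china L., and the labels do not say what diet the SCL-treated rats ate. The text on the study's design names an SCS group where the sample labels say SCL, and the 2 were taken here as the same group, which the labels do not state. The high-fat diet was given to induce fatty liver disease. The labels call the tissue of both the high-fat diet and the SCL-treated samples fatty liver. Total counts were 14998408, 15204882 and 13846073 reads in normal diet replicates 1, 2 and 3, and 15521648, 13415699 and 12842031 reads in the high-fat diet replicates. They were 14298140, 12413774 and 12802465 reads in the SCL-treated replicates. Between 13239 and 14409 genes had at least 1 read in a library.

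Transcripts of the mitochondrial genome took very different shares of the libraries. They made up 4.63%, 3.85% and 11.2% of reads in normal diet replicates 1, 2 and 3, and 4.90%, 18.8% and 44.1% in the high-fat diet replicates. In the SCL-treated replicates they made up 10.97%, 49.0% and 7.04%. The mean was 6.54% ± 4.01 (SD, n = 3) on the normal diet, 22.6% ± 19.9 (SD, n = 3) on the high-fat diet and 22.3% ± 23.2 (SD, n = 3) with SCL. A two-sided exact permutation test gave p = 0.2 for high-fat against normal diet, p = 1 for SCL-treated against high-fat diet and p = 0.3 for SCL-treated against normal diet. The smallest p that 3 against 3 libraries allow is 0.1. The labels say that rats were divided at random, but beyond the sample numbering nothing states that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

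**Figure D1:**
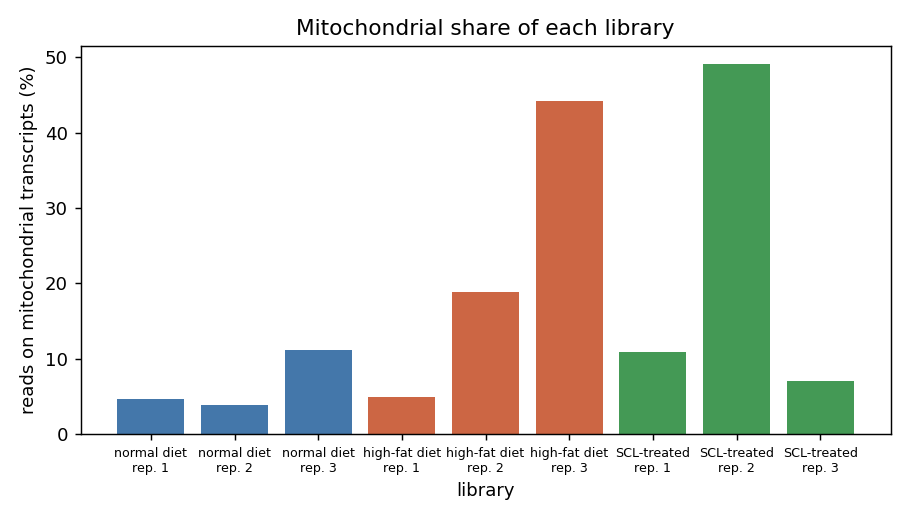
Each bar is the percentage of a library's reads that lay on mitochondrial genome transcripts, with the libraries coloured by group along the horizontal axis. High-fat diet replicate 3 reached 44.1% and SCL-treated replicate 2 reached 49.0%, while normal diet replicate 2 held 3.85%.

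The first comparison asked what the high-fat diet changed in the liver. Genes of cholesterol synthesis were lower in high-fat diet livers. All 25 tested members of the list had a negative log2 fold change, with a median of -1.71 (camera adjusted p = 1.1e-56). Tm7sf2, a sterol reductase of the pathway, fell by 3.82 on the log2 scale (SE 0.37, n = 3 against 3, edgeR adjusted p = 0.0083). Its mean was 110.9 ± 32.7 CPM (SD) on the normal diet and 7.83 ± 2.93 CPM (SD) on the high-fat diet, and it was the only one of 12041 genes past the edgeR threshold. Adjusted over the list alone, 19 members were lower and 0 higher.

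Of those 19, the members named here besides Tm7sf2 were chosen after their values were seen. Sqle, the squalene epoxidase, had a log2 fold change of -3.65 (SE 0.56, adjusted p = 3.1e-04 over the list alone and 0.15 over all genes). The lanosterol demethylase gene Cyp51 stood at -3.29 (SE 0.41, adjusted p = 1.1e-04 over the list alone and 0.052 over all genes). Insig1, which holds back the activation of sterol regulatory proteins, stood at -2.27 (SE 0.48, adjusted p = 0.0023 over the list alone).

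With an estimated correlation the cholesterol synthesis list had an adjusted p of 0.046, and it was the only list called in that test. That call held in 2 of 9 fits that each left out 1 library, where adjusted p ran from 0.037 to 0.59, and ended without the 2 libraries over 40% mitochondrial (adjusted p = 0.12). With the mitochondrial share as covariate, chosen after seeing the data, the call was kept (adjusted p = 0.017 with an estimated correlation, fry adjusted p = 0.034). The list median lay between -1.85 and -1.57 in those 9 fits and at -1.56 without the 2 libraries. Tm7sf2 lost its call without high-fat diet replicate 2 (adjusted p = 0.078), with library totals as the only scaling (adjusted p = 0.094) and with only the 6 libraries compared (adjusted p = 0.13). Without the 2 libraries over 40% mitochondrial no gene was called and Tm7sf2 had an adjusted p of 0.064. Its log2 fold change was -3.61 there and -3.76 without high-fat diet replicate 2, against -3.82 with all libraries.

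Genes of fatty acid synthesis did not pass as a group on the high-fat diet, with a median of -0.32 over 17 tested genes (camera adjusted p = 0.055). Adjusted over the list alone, 1 gene was higher and 2 were lower, and these were named after their values were seen. Scd, the stearoyl-CoA desaturase, stood at 3.23 (SE 0.97, adjusted p = 0.040 over the list alone), with 93.0 ± 24.2 CPM (SD) on the normal diet and 873.6 ± 772.6 CPM (SD) on the high-fat diet. Its high-fat diet replicates had 1585.7, 983.0 and 52.1 CPM, the last below each normal diet library (73.2, 119.9 and 85.9 CPM). Fads1, a desaturase of polyunsaturated fatty acids, stood at -2.44 (SE 0.48, adjusted p = 0.0063 over the list alone), and Acss2, which makes acetyl-CoA from acetate, at -1.25 (SE 0.37, adjusted p = 0.040 over the list alone). Srebf1, one of the 2 most abundant members, had a log2 fold change of 2.21 (SE 0.86) and did not pass.

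Other lists of liver metabolism had camera calls that an estimated correlation did not keep. Fatty acid oxidation and PPAR alpha targets had a median of -0.22 (camera adjusted p = 0.021, adjusted p = 0.63 with an estimated correlation), with Cyp4a2 at -0.95 (SE 0.54). Glucose production and insulin signalling had a median of -0.29 (camera adjusted p = 0.028, adjusted p = 0.63 with an estimated correlation), with Pck1, an enzyme of gluconeogenesis, at -1.14 (SE 0.42). Acute-phase proteins had a median of -0.70 (camera adjusted p = 9.0e-07, adjusted p = 0.63 with an estimated correlation), with Serpina1 at -0.54 (SE 0.48) and Hp at -0.47 (SE 0.45). The cell cycle list had a median of 0.65 (camera adjusted p = 0.011, adjusted p = 0.53 with an estimated correlation), with Aurka at 0.71 (SE 0.39) and Pcna at -0.15 (SE 0.32). Transcripts of the mitochondrial genome had a median of 1.98 (camera adjusted p = 1.7e-06, adjusted p = 0.63 with an estimated correlation), with Mt-co1 at 1.79 (SE 1.00). With the mitochondrial share as covariate glucose production and insulin signalling lost its call (-0.099, camera adjusted p = 0.64), and acute-phase proteins stood at -0.29 (camera adjusted p = 0.012). Without the 2 libraries over 40% mitochondrial glucose production stood at -0.14 (camera adjusted p = 0.19) and mitochondrial genome transcripts at 0.97 (camera adjusted p = 4.2e-04), and without high-fat diet replicate 3 alone the latter also stood at 0.97. Fatty acid oxidation lost its camera call without normal diet replicate 3 (-0.021), high-fat diet replicate 1 (-0.18) or 2 (-0.11), and the cell cycle without high-fat diet replicate 1 (0.77, adjusted p = 0.095). Without normal diet replicate 3 the cell cycle stood at 1.02. Glucose production lost its call without normal diet replicate 1 (-0.063) or 2 (-0.31) or high-fat diet replicate 2 (-0.26) or 3 (-0.14), and stood at -0.52 without normal diet replicate 3 and -0.65 without high-fat diet replicate 1. Fatty acid oxidation (-0.20, camera adjusted p = 0.0032) and the cell cycle (0.66, 8.6e-05) kept their calls with the covariate. Both kept them without the 2 libraries over 40% mitochondrial (-0.32, 3.0e-06, and 0.94, 3.1e-08), as did acute-phase proteins (-0.48, 2.0e-06). None was called in either setting with an estimated correlation (lowest adjusted p = 0.089). Mitochondrial genome transcripts, which make up the share, lost their call with the covariate (0.042, 0.93). These 5 lists stood beside a mean mitochondrial share of 6.54% on the normal diet and 22.6% on the high-fat diet.

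Markers of hepatocytes and of some other cell types had lower medians in the same comparison. All 12 hepatocyte markers were lower, with a median of -0.52 (camera adjusted p = 0.0018, adjusted p = 0.63 with an estimated correlation), and Alb stood at -0.53 (SE 0.64). Kupffer cell and macrophage markers had a median of -0.47 (camera adjusted p = 3.1e-04, adjusted p = 0.63 with an estimated correlation), with Clec4f at -0.998 (SE 0.51). Sinusoidal endothelium markers had a median of -0.29 and periportal hepatocyte genes one of -0.56, each with a camera adjusted p of 0.014 and an adjusted p of 0.63 with an estimated correlation. With the mitochondrial share as covariate none of these 4 lists kept its camera call, with hepatocyte markers at -0.098 (adjusted p = 0.64), Kupffer cell markers at -0.14 (0.089), sinusoidal markers at -0.20 (0.17) and periportal genes at -0.18 (0.62). Without the 2 libraries over 40% mitochondrial hepatocyte markers stood at -0.23 (camera adjusted p = 0.051), Kupffer cell markers at -0.23 (0.0070), sinusoidal markers at -0.21 (0.090) and periportal genes at -0.26 (0.47). Without high-fat diet replicate 3 alone they stood at -0.24 (camera adjusted p = 0.14), -0.23 (0.030), -0.21 (0.092) and -0.26 (0.54). Without high-fat diet replicate 1 Kupffer cell markers (-0.63, camera adjusted p = 0.073) and sinusoidal markers (-0.32, 0.053) lost their calls, and without replicate 2 Kupffer cell markers stood at -0.73. These 4 lists stood beside the same mean shares of 6.54% and 22.6%. Markers of neutrophils (median 1.14 over 3 tested genes, with an estimated correlation between them of 0.92), T and NK cells (0.42), B and plasma cells (0.51), cholangiocytes (0.43), erythroid cells (0.88) and adipocytes (0.39) did not pass, nor did pericentral hepatocyte genes (-0.12, with a mean of 0.13 and an upward camera direction). The exocrine pancreas list had 2 tested members, with a median of 0.12, too few for the test.

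The remaining lists had a camera adjusted p over 0.05. Their medians were 0.088 for lipid uptake, storage and lipid droplets, -0.25 for lipoproteins, -0.29 for bile acid synthesis and transport, and -0.19 for cytochrome P450 families 1 to 3. They were 0.065 for antioxidant and NRF2 targets (camera adjusted p = 0.13), -0.19 for the unfolded protein and integrated stress response, 0.096 for inflammatory cytokines and NF-kB targets (mean -0.037 and a downward camera direction), and -0.13 for the interferon response. They were -0.32 for extracellular matrix and stellate cell genes, 0.10 for the circadian clock and 0.15 for the nuclear-encoded respiratory chain. Antioxidant and NRF2 targets had a median of 0.36 with the mitochondrial share as covariate (camera adjusted p = 4.1e-05, adjusted p = 0.71 with an estimated correlation). Without the 2 libraries over 40% mitochondrial it was 0.27 (camera adjusted p = 0.0094, adjusted p = 0.46 with an estimated correlation). With the same covariate extracellular matrix and stellate cell genes stood at -0.45 (camera adjusted p = 1.5e-07, adjusted p = 0.65 with an estimated correlation) and interferon response genes at 0.30 (camera adjusted p = 0.0049, adjusted p = 0.73 with an estimated correlation). Adjusted over the list alone, Slc27a5 (-1.47, SE 0.35), Cyp2c12 (-2.70, SE 0.51) and Socs3 (-1.88, SE 0.46) were lower and Per2 (2.64, SE 0.57) was higher, each the single call of its list and named after its value was seen.

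Without the 2 libraries over 40% mitochondrial camera called 7 lists in place of 10. In all, edgeR called 1 gene between high-fat and normal diet, and 520 genes had an unadjusted p under 0.05, 333 higher and 187 lower. The groups did not overlap at 10.6% of genes, where chance gives 10%. DESeq2 called 48 genes, 27 higher and 21 lower, and limma-voom with quality weights called 26. Of the 25 cholesterol synthesis members DESeq2 called 11 and limma-voom 9, adjusted over all genes. The authors' deposited table held 53 genes with an adjusted p under 0.05, of which 43 were among the 48 called by DESeq2 here, all 43 in the same direction. On simulated data for this comparison edgeR recovered 4.48% of genes changed 2-fold, 29.9% of those changed 4-fold and 86.4% of those changed 8-fold, and DESeq2 recovered 19.4%, 64.2% and 93.9%. These rates rest on independent simulated genes and on the number of genes changed, and may not carry over to the real libraries. Sqle and Cyp51, with estimated falls over 8-fold, did not pass edgeR over all genes. Of 11816 genes simulated without change DESeq2 called 36 and edgeR 3, so some of the 48 DESeq2 calls may be false. Beside them 67, 67 and 66 genes were changed 2-fold, 4-fold and 8-fold, and 25 list genes were lowered. Calls of changed genes ease the adjusted threshold for unchanged ones, so 36 does not give the number of false calls among the 48.

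The second comparison asked what SCL changed against the high-fat diet. Cholesterol synthesis genes had a median log2 fold change of 0.23 over 25 genes, 16 of them higher (camera adjusted p = 0.014, adjusted p = 0.80 with an estimated correlation). Hmgcs1 stood at -0.50 (SE 0.37) and Tm7sf2 at 0.43 (SE 0.34). Scd averaged 212.8 ± 153.8 CPM (SD) with SCL and 873.6 ± 772.6 CPM (SD) on the high-fat diet, a log2 fold change of -2.04 (SE 0.93) that did not pass. No gene passed the edgeR threshold (lowest adjusted p = 1.00), and 235 of 12041 genes had an unadjusted p under 0.05, 74 higher and 161 lower. These 235 were 1.95% of genes, fewer than a threshold of 0.05 lets through by chance. The groups did not overlap at 4.78% of genes, where chance gives 10%.

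Camera called 8 lists in this comparison, all upward, and none with an estimated correlation, where the lowest adjusted p was 0.66. Besides cholesterol synthesis these were bile acid synthesis and transport (median 0.31, with Baat at -0.0057, SE 0.40, and Akr1d1 at 0.29, SE 0.38), cytochrome P450 families 1 to 3 (0.22, with Cyp2e1 at 0.60, SE 0.35), and antioxidant and NRF2 targets (0.21, with Gpx1 at 0.66, SE 0.52). Acute-phase proteins (0.34, with Hp at 0.41, SE 0.45) and periportal hepatocyte genes (0.33) were also called. The camera adjusted p of these 5 lists was 0.010. The nuclear-encoded respiratory chain had a median of 0.22 (camera adjusted p = 0.019) and erythroid markers one of 0.64 over 4 genes (camera adjusted p = 0.024, Hbb at 1.01, SE 0.50). Fatty acid synthesis genes had a median of -0.51 and hepatocyte markers one of 0.35, and neither passed. Camera called both without the 2 libraries over 40% mitochondrial, at -0.83 (adjusted p = 0.0034, adjusted p = 0.49 with an estimated correlation) and 0.41 (adjusted p = 0.0069, adjusted p = 0.47 with an estimated correlation). Of the 14 lists called then 11 were upward and 3 downward, the others downward being extracellular matrix and stellate cell genes (-0.40, adjusted p = 0.47 with an estimated correlation) and the cell cycle (-0.47, against 0.049 with all libraries, adjusted p = 0.34 with an estimated correlation). Upward calls gained there were lipoproteins (0.021, adjusted p = 0.41 with an estimated correlation), interferon response genes (0.22, 0.49), neutrophil markers (0.93, against -0.27 over 3 genes with all libraries, 0.47) and B and plasma cell markers (1.15, 0.43). Camera's direction with all libraries was already downward for the cell cycle and upward for neutrophil markers, against the sign of their medians. Periportal genes lost their call there (0.27, camera adjusted p = 0.28), and bile acid synthesis stood at 0.17 (camera adjusted p = 0.0098). With the mitochondrial share as covariate fatty acid synthesis stood at -0.18 (camera adjusted p = 0.25). Each of the 8 lists lost its call without some single library. Without SCL-treated replicate 3 the medians that lost it were 0.21 for bile acid synthesis, 0.035 for cytochrome P450 families, -0.068 for antioxidant targets, -0.035 for acute-phase proteins, 0.0041 for the respiratory chain and 0.25 for periportal genes. Without high-fat diet replicate 3 they were 0.12 for cytochrome P450 families, 0.097 for antioxidant targets, 0.14 for acute-phase proteins, 0.10 for the respiratory chain and 0.0052 for periportal genes. Without SCL-treated replicate 1 they were 0.10 for cytochrome P450 families, 0.18 for antioxidant targets, 0.35 for acute-phase proteins, 0.15 for the respiratory chain, 0.61 for erythroid markers and 0.24 for periportal genes. Without high-fat diet replicate 1 antioxidant targets (0.36), the respiratory chain (0.12) and erythroid markers (-0.055) lost it, and without high-fat diet replicate 2 bile acid synthesis (0.25) and erythroid markers (0.38). Erythroid markers also lost it without SCL-treated replicate 2 (0.26) and normal diet replicate 3 (0.45). Other medians that moved while the call stayed were 0.46 for cytochrome P450 families, 0.40 for antioxidant targets, 0.60 for acute-phase proteins, 0.36 for the respiratory chain and 0.55 for periportal genes without SCL-treated replicate 2. They were 0.42 for cytochrome P450 families, 0.38 for antioxidant targets, 0.53 for acute-phase proteins and 0.34 for the respiratory chain without high-fat diet replicate 2. They were 0.52 for bile acid synthesis, 0.40 for cytochrome P450 families and 0.62 for periportal genes without high-fat diet replicate 1. Erythroid markers stood at 1.24 and bile acid synthesis at 0.21 without high-fat diet replicate 3, and erythroid markers at 1.03 without SCL-treated replicate 3. The mean mitochondrial share was 22.6% on the high-fat diet and 22.3% with SCL, with 1 library over 40% in each group.

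DESeq2 called 1 gene between SCL-treated and high-fat diet livers, Eml5, named after its value was seen. It stood at -1.80 in edgeR (SE 0.32, adjusted p = 1.00) and had an adjusted p of 0.0045 in DESeq2, with 14.8 ± 0.705 CPM (SD) on the high-fat diet and 4.25 ± 1.55 CPM (SD) with SCL. Of 11816 genes simulated without change in this comparison DESeq2 called 34 and edgeR 11. Those data also held genes changed by known folds, so the counts do not carry over to the real data, but Eml5 may still be a false call. Limma-voom with quality weights called 0 genes, and the authors' deposited table held 0 genes with an adjusted p under 0.05, with a lowest adjusted p of 0.211. On simulated data for this comparison edgeR recovered 1.49% of genes changed 2-fold, 55.2% of those changed 4-fold and 81.8% of those changed 8-fold. These rates too rest on independent simulated genes and may not carry over to the real libraries. Camera called 2 lists in place of 8 without SCL-treated replicate 1, 12 without high-fat diet replicate 2, and 14 without the 2 libraries over 40% mitochondrial, where edgeR called 0 genes. Cholesterol synthesis lost its camera call without high-fat diet replicate 3 (median 0.17, adjusted p = 0.48) and without SCL-treated replicate 3 (median -0.026, adjusted p = 0.44). It also lost the call without the 2 libraries over 40% mitochondrial (median 0.29, adjusted p = 0.096).

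**Figure D2:**
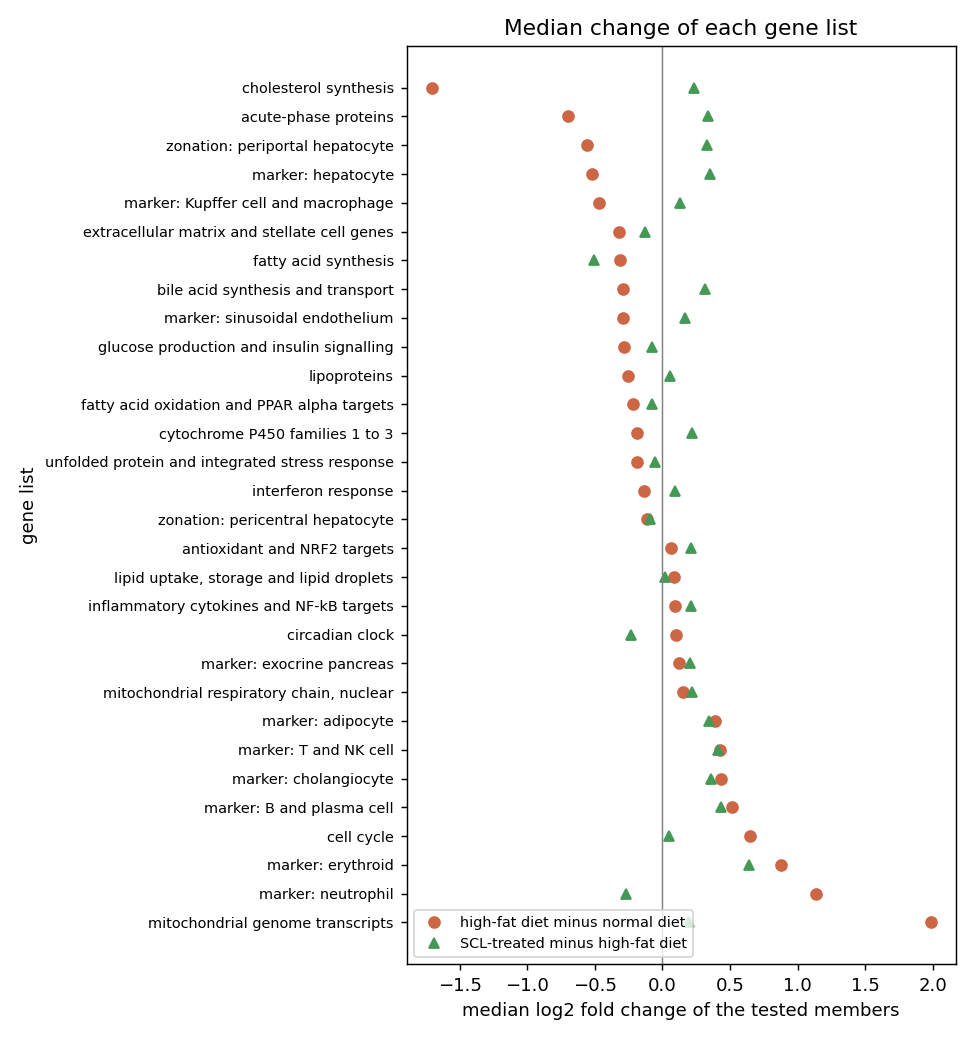
Each row is a gene list, and its points give the median log2 fold change of its tested members, as circles for high-fat diet minus normal diet and triangles for SCL-treated minus high-fat diet. Cholesterol synthesis stood at -1.71 in the first comparison and at 0.23 in the second.

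The third comparison set SCL-treated against normal diet livers. It used the same 3 normal diet libraries as the first, so the results of the 2 comparisons are not independent. The labels do not give the diet of the SCL-treated rats, so differences from the normal diet livers cannot be assigned to SCL. Cholesterol synthesis genes were lower in SCL-treated than in normal diet livers, with all 25 members below 0 and a median of -1.50 (camera adjusted p = 1.1e-34, adjusted p = 0.16 with an estimated correlation), and 19 were lower when adjusted over the list alone. Tm7sf2 fell by 3.39 on the log2 scale (edgeR adjusted p = 0.022), from 110.9 ± 32.7 to 10.6 ± 2.18 CPM (SD, n = 3 per group), and was the only gene called. Tm7sf2 was called in 3 of the 9 fits that left out 1 library, with adjusted p from 0.0047 to 0.20, and not without the 2 libraries over 40% mitochondrial (adjusted p = 0.18). Its log2 fold change ran from -3.58 to -3.13 in the 9 fits and was -3.28 without the 2 libraries. Antioxidant and NRF2 targets had a median of 0.55 (camera adjusted p = 0.0015, adjusted p = 0.59 with an estimated correlation). B and plasma cell markers had a median of 0.98 (camera adjusted p = 0.0078, adjusted p = 0.59 with an estimated correlation). Transcripts of the mitochondrial genome (median 2.16, camera adjusted p = 5.5e-06), erythroid markers (1.40, 0.0046), T and NK cell markers (0.80, 0.028) and cholangiocyte markers (0.92, 0.043) were also called upward, and Kupffer cell and macrophage markers downward (-0.35, 0.014). Each of these 5 had an adjusted p of 0.59 with an estimated correlation, and the mean mitochondrial share was 6.54% on the normal diet and 22.3% with SCL. With that share as covariate T and NK cell markers (0.41, camera adjusted p = 0.34), B and plasma cell markers (0.81, 0.081), cholangiocyte markers (-0.090, 0.84) and Kupffer cell markers (-0.13, 0.34) lost their calls. Erythroid markers stood at 0.64 (camera adjusted p = 0.034) with it. Cholangiocyte markers (0.036, camera adjusted p = 0.53) and Kupffer cell markers (-0.16, 0.12) lost their calls without the 2 libraries over 40% mitochondrial, and mitochondrial genome transcripts stood at 0.67 (0.0052). Antioxidant targets kept their call with the covariate (0.54, camera adjusted p = 3.2e-10) and without the 2 libraries (0.74, 2.7e-10). With an estimated correlation their adjusted p was 0.38 and 0.27 there. They lost their call without SCL-treated replicate 3 (0.081, camera adjusted p = 0.19), and B and plasma cell markers (0.64, 0.12) and T and NK cell markers (0.59, 0.18) lost theirs without SCL-treated replicate 1. Cholangiocyte markers (0.045, 0.56) and Kupffer cell markers (-0.15, 0.14) lost theirs without SCL-treated replicate 2, and T and NK cell markers (0.69, 0.10) and cholangiocyte markers (0.98, 0.095) without normal diet replicate 2, where B and plasma cell markers stood at 0.50. With SCL-treated replicate 3 left out cholangiocyte markers stood at 1.49 and Kupffer cell markers at -0.77, and with replicate 2 left out mitochondrial genome transcripts stood at 0.68.

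Lists of liver metabolism were also called between SCL-treated and normal diet livers. Fatty acid synthesis had a median of -0.87 (camera adjusted p = 0.0080), fatty acid oxidation and PPAR alpha targets one of -0.29 (0.0024) and glucose production and insulin signalling one of -0.36 (0.016), each with an adjusted p of 0.59 with an estimated correlation. Acute-phase proteins had a median of -0.29 (camera adjusted p = 0.028) and the nuclear-encoded respiratory chain one of 0.26 (0.015), each with an adjusted p of 0.70 with an estimated correlation. With the mitochondrial share as covariate fatty acid synthesis (-0.18, camera adjusted p = 0.89), glucose production (-0.31, 0.34) and acute-phase proteins (-0.012, 0.84) lost their calls. Fatty acid synthesis (-0.86, camera adjusted p = 0.066), fatty acid oxidation (-0.21, 0.054) and acute-phase proteins (-0.016, 0.77) lost theirs without the 2 libraries over 40% mitochondrial, where glucose production stood at -0.61 and the respiratory chain at 0.52. Fatty acid synthesis also lost its call without normal diet replicate 1 (-0.60) or SCL-treated replicate 1 (-0.64), and fatty acid oxidation without SCL-treated replicate 2 (-0.21), while it stood at -0.53 without SCL-treated replicate 1. Glucose production lost its call without normal diet replicate 1 (-0.40) or SCL-treated replicate 1 (-0.49), and stood at -0.60 without SCL-treated replicate 2. Acute-phase proteins lost theirs without SCL-treated replicate 2 (-0.0071), high-fat diet replicate 1 (-0.29) or normal diet replicate 3 (-0.32), and stood at -0.69 without SCL-treated replicate 3. The respiratory chain lost its call without normal diet replicate 1 (0.087), SCL-treated replicate 1 (0.095) or SCL-treated replicate 3 (0.093), and stood at 0.53 without SCL-treated replicate 2 and 0.50 without normal diet replicate 3. Extracellular matrix and stellate cell genes (-0.36, camera adjusted p = 0.0504) did not pass, nor did interferon response genes (-0.0023), cytochrome P450 families 1 to 3 (-0.0046) or the cell cycle (0.52). With the covariate camera called these 4 at -0.44, 0.28, 0.20 and 0.46, with an adjusted p of 0.41, 0.41, 0.62 and 0.38 with an estimated correlation. Extracellular matrix genes (-0.70) and interferon response genes (0.23) were called without the 2 libraries, with an adjusted p of 0.51 and 0.63 with an estimated correlation.

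In all 828 genes had an unadjusted p under 0.05 between SCL-treated and normal diet livers, DESeq2 called 36 and limma-voom with quality weights called 152. Of the 25 cholesterol synthesis members DESeq2 called 7 and limma-voom 16, adjusted over all genes. In the simulation of this comparison DESeq2 called 42 of 11816 unchanged genes and edgeR 7. Other genes were changed there, so these counts do not carry over, but some of the 36 calls may be false. Camera called 13 lists, 7 up and 6 down, and none was called with an estimated correlation.

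The last question was whether genes changed by the diet moved back under SCL. No gene was called by edgeR in both comparisons, in either direction, nor by DESeq2 or limma-voom with quality weights. For edgeR and limma-voom this was fixed by their 0 calls between SCL-treated and high-fat diet, where DESeq2 had 1, so it says nothing of whether genes moved back. At an unadjusted p under 0.05, 42 genes moved in opposite directions and 2 in the same direction. Both comparisons share the high-fat diet libraries, and simulated libraries with no effect gave 117.9 and 1.2 genes. Independent lists would give 4.45 genes higher on the diet and lower with SCL, where 22 were seen, and 1.15 genes lower on the diet and higher with SCL, where 20 were seen. The covariance of the log2 fold changes was -0.056, against a simulated -0.16 (SD 0.0028), and the correlation across genes was -0.18 against a simulated -0.50. The 3 high-fat diet libraries could not be split into 2 sets of at least 2. In simulation the shared libraries alone gave more opposite genes than were seen. The simulation drew each gene independently, while the first principal component held 48.0% of the variance of the real libraries. Its SD may therefore be too narrow, and 117.9 is no firm expectation for the 42 seen. Whether genes moved back stays open.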

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

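Alternatives with the mitochondrial share, without the 2 libraries over 40% mitochondrial and without mitochondrial transcripts were chosen after seeing the data. Between high-fat and normal diet edgeR called 1 gene. DESeq2 called 48 and limma-voom with quality weights 26, of which 19 were shared. No count filter gave 2, and library totals only, the 6 libraries compared, and the removal of the 2 libraries over 40% mitochondrial each gave 0. Leaving out 1 library gave 1 to 4 genes, with 4 without normal diet replicate 3, 2 without high-fat diet replicate 3 and 1 in each other fit. That gene was Tm7sf2 except without high-fat diet replicate 2, where Rn60_9_0652.2 was called instead. Between SCL-treated and high-fat diet livers edgeR called 0 genes in every setting, and DESeq2 called 1. Between SCL-treated and normal diet livers edgeR called 1 gene, DESeq2 36 and limma-voom with quality weights 152, with 32 shared. That count was 0 with library totals only, at an adjusted p under 0.01, and without the 2 libraries over 40% mitochondrial. It ran from 0 to 1 with 1 library left out. The 10 lists called between high-fat and normal diet became 1 with an estimated correlation and 1 with fry. The 8 lists called between SCL-treated and high-fat diet became 0 with an estimated correlation, 0 with fry and 14 without the 2 libraries over 40% mitochondrial, and ran from 2 to 12 with 1 library left out, with 2 without SCL-treated replicate 1 and 12 without high-fat diet replicate 2. The count of genes that moved back was 0 in every setting that gave one, as it had to be where 0 genes were called between SCL-treated and high-fat diet. The cause was not tested. Correlations of the deviations of same-numbered libraries ran from -0.35 to 0.60. Those of differently numbered libraries were not computed, so whether same-numbered libraries pair cannot be told. With the replicate block edgeR called 1, 0 and 1 genes in the 3 comparisons and camera 12 and 8 lists. Mitochondrial genome transcripts in SCL-treated against high-fat diet livers had a median of 0.20, which ran from -1.38 to 1.20 with 1 library left out, with -1.38 without SCL-treated replicate 2, and was -0.91 with limma-voom. Interferon response genes turned to 0.30 against the normal diet on the high-fat diet with the mitochondrial share as covariate. With SCL they ran from -0.29 to 0.24 with 1 library left out, with 0.24 without SCL-treated replicate 2, and were 0.28 with the covariate and 0.23 without the 2 libraries over 40% mitochondrial. With the covariate the SCL-treated minus normal diet medians of fatty acid synthesis and cholangiocyte markers became -0.18 and -0.090. Library totals only moved the median of all genes to -0.19 in SCL-treated against high-fat diet and -0.21 against normal diet, from -0.031 and 0.026. Between SCL-treated and high-fat diet the cell cycle median of 0.049 and the neutrophil median of -0.27 over 3 genes became -0.47 and 0.93, both called, without the 2 libraries over 40% mitochondrial, and -0.35 and 0.85, both called, without high-fat diet replicate 3. With all libraries camera's direction was already downward for the cell cycle and upward for neutrophil markers, though neither was called. The cell cycle was also called at -0.32 without SCL-treated replicate 3 and -0.037 without normal diet replicate 2. Over all alternatives 6538 values of lists and genes were compared with those first given, with direction taken from camera for lists. With a call on either side 8 values of lists turned direction, as given above. Calls were lost by 150 values of lists and 12 of genes and gained by 87 and 148, and 342 values turned direction with neither past the threshold.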

Other observations

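Of the tests in this part, those of the mitochondrial share as covariate, hepatocyte RNA, group differences in the share, crowding out, 3 further LXR targets, and regroupings for the count of genes in SCL-treated against high-fat diet and for genes that moved back were chosen after the result was seen.

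DESeq2 called genes between high-fat and normal diet that belong to none of the lists, named here after their values were seen. Adam8, a membrane protease, had 0.517 ± 0.151 CPM (SD, n = 3) on the normal diet, 5.39 ± 3.03 on the high-fat diet and 2.04 ± 0.422 with SCL. Tex13b stood at 1.67 ± 0.755, 22.9 ± 19.5 and 18.2 ± 11.2 CPM, and Chka, a choline kinase, at 84.9 ± 14.3, 443.9 ± 303.0 and 219.4 ± 135.9 CPM. Acsf2, an acyl-CoA synthetase, stood at 30.4 ± 19.4, 6.18 ± 2.36 and 5.50 ± 1.94 CPM. Their DESeq2 adjusted p was 8.8e-05 for Adam8, 1.7e-05 for Tex13b, 0.022 for Chka and 0.0092 for Acsf2, while edgeR's was 0.26, 0.32, 0.75 and 0.61. The high-fat diet replicates of Tex13b had 8.94, 14.7 and 45.2 CPM, so its mean rests much on replicate 3. EdgeR called none of these genes, so any of them may be a false call. In simulation DESeq2 called 36 of 11816 unchanged genes for this comparison, a count that does not carry over to the real calls.

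Cholesterol synthesis genes were lower on the high-fat diet, with a list median of -1.71. The tables argue against the mitochondrial share as the whole cause, since with its log2 as covariate the median was -1.32 (-1.45 to -1.16 with each library left out), and against a general loss of hepatocyte RNA, since the list median minus the hepatocyte marker median was -1.19 (-1.34 to -1.05). A candidate explanation is more sterol in the liver, and 7 LXR target genes, which rise with sterol, met the bound set in advance against it, a median at or below 0, with -0.43 (-0.71 to -0.15 with each library left out), 5 of 7 lower and 5 of 7 in lists whose medians had been seen. Camera at the preset correlation gave the 7 genes an unadjusted p of 0.0088, downward. Only after these values were seen was the sterol explanation left open. The bound was then held wrong for a list that had missed the LXR targets Cyp7a1, Srebf1 and Scd. These stood at 1.94 (SE 0.62), 2.21 (SE 0.86) and 3.23 (SE 0.97), each with an edgeR adjusted p of 0.91 over all genes. With them the median was -0.058 and ran from -0.31 to 0.11. They too belong to lists whose medians had been seen, and Scd in high-fat diet replicate 3 lay below each normal diet library, so they give no test of the explanation. The diet itself stays open and untested. Of the 10 splits of the 6 libraries 1 gave a median as far from 0, the real one at 1.71, and the highest other was 1.25, too few splits for a share under 0.05. That other split set the libraries of lowest mitochondrial share, normal diet replicates 1 and 2 and high-fat diet replicate 1, against the rest. The list was lower in the libraries of higher share (-1.25). Because the split also mixed the diets unevenly, its median does not tell share from diet.

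The mitochondrial share ran from 3.85% to 49.0% of reads. Crowding out of other transcripts alone was argued against, since without mitochondrial transcripts the first principal component still followed the share (absolute Spearman rho 0.93, from 0.88 to 0.98 with each library left out, exact permutation p = 7.5e-04). Pearson's r over the 9 libraries was 0.88 (exact permutation p = 5.8e-05), and 0.92 without the 2 libraries farthest from the median share. Group differences stay open, with 72.3% of the variance of the log2 share within groups (48.4% to 84.1%). A loss of transcripts made at the endoplasmic reticulum may contribute and stays open, as the slopes of Slc and Tmem genes lay -0.044 log2 per doubling from those of Psm, Eif and Ube2 genes (-0.11 to -0.019), and gene length stays open too, with a rank correlation across genes of -0.017 that ran from -0.21 to 0.17, where genes are not independent replicates.

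Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In high-fat against normal diet 2 of 10 splits called as many genes as the real 1, and the highest other called 1629. It set normal diet replicates 1 and 2 and high-fat diet replicate 1, with the 3 lowest mitochondrial shares of the 6 (4.63%, 3.85% and 4.90%), against the rest (11.2%, 18.8% and 44.1%). The sample titles give high-fat diet replicate 1 the prefix M2 and the other high-fat diet libraries the prefix M, without saying what this means, and that library had a limma-voom weight of 0.28 and, like normal diet replicate 1, a first-component score of -0.42. SCL-treated replicate 2 had a weight nearly as low, at 0.30. For lists 3 of 10 called as many as the real 10, with 13 as the highest other. In SCL-treated against high-fat diet 10 of 10 splits called as many genes as the real 0, as any count does. The highest other called 946, and again set the 3 lowest shares, those of high-fat diet replicate 1 and SCL-treated replicates 1 and 3 (4.90%, 10.97% and 7.04%), against the rest (18.8%, 44.1% and 49.0%). For lists 7 of 10 called as many as the real 8, with 19 as the highest other. In SCL-treated against normal diet 1 of 10 called as many genes as the real 1, and the highest other called 0. For lists the real split called 13, further splits also called 13, and the highest other called 15. For genes that moved back, all 100 assignments of the 9 libraries gave at least the real 0, as any count does, and the highest gave 841.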
